A study of Danio rerio with 6 samples.

How the data were processed

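RNA from 6 zebrafish liver samples, 3 ATG5 and 3 WT, was sequenced after TRIzol extraction and preparation with a stranded total RNA kit, per the labels' protocols. The deposited table holds estimated counts per Ensembl gene, which need not be whole numbers. The submitters' processing notes name FastQC 0.11.5, kallisto 0.45.0, sleuth 0.30.0 and the build GRCz11, without their order. The strand setting of the counting is not given in the sources used here, so overlapping antisense genes cannot be told apart, and estimated counts of near-identical paralogues are uncertain because reads can be split between them. The table held 30628 genes, of which 23608 (77.1%) matched a symbol. A total of 1778 genes repeat the symbol of a gene listed before them, the first gene of each such symbol not counted. No coordinates are given, since the annotation table at hand is of another build (GRCz12tu), used only for synonyms and for the order of genes.

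Columns were matched to samples by the sample descriptions, and groups came from the titles. The deposited estimated counts were rounded to whole numbers. Totals per library ran from 33668961 to 44763253, and 3 counts in a library corresponded to 0.067 to 0.0891 CPM before TMM scaling, a limit that covers counting error only. Pairs of libraries were compared by chi-square over genes, and none agreed within sampling noise.

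Genes were filtered with filterByExpr, leaving 20366, and scaled with TMM factors. The groups were compared in R 4.3.3 with edgeR 4.0.16 (glmQLFit and glmQLFTest, design of group only) and Benjamini-Hochberg adjustment at 0.05, with a log2 fold minimum of 1 for the smaller count. Levels are TMM-normalised CPM with SD. Standard errors of log2 folds come from the spread of log2 CPM (prior count 2) within the groups, which narrows them for genes near 0 counts in a group. A gene with no count in a group was given a bound against 3 counts over that group. Setting such genes at their bound moved no list median. The 45 gene lists, 2183 members of which 2010 (92.1%) matched, were fixed before the data were examined, as were the tests, the alternatives listed below and the rule for named genes. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, again with an estimated correlation, and with fry. Some genes belong to more than 1 list.

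The rule for named genes took atg5, then, among called genes with groups that did not overlap, a mean of at least 5 CPM in the higher group and a named symbol, the 10 with the largest fold and the 5 with the smallest p in each direction. It added up to 4 called members per list with the smallest p, or 2 by abundance in a list with no call, and the 5 most abundant genes. Not all are named, and some are not reported here.

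The steps were tested on simulated data drawn from the real means, library sizes and fitted dispersions. With 200 changed genes among 19829 tested, the test of ATG5 against WT recovered 0% of genes changed 1.5-fold, 2% at 2-fold, 38% at 4-fold and 66% at 8-fold. Recovery rose with a smaller spread and with more changed genes. With a small dispersion of 0.01 the same code recovered 66%, 98%, 100% and 100% among 20111 genes, and 4.74% of unchanged genes had an unadjusted p under 0.05. With the fitted spread and 6000 changed genes, nearer the number called in the data, recovery among 19914 genes was 7.33%, 30.6%, 84.3% and 95.3%, with 3.35% of calls false. The fitted dispersions (median 0.0815 for genes over 30 counts) lay above moment estimates within groups (0.0274 and 0.0333), so the simulated recovery may be too low. The list test called 10 of 10 shifted and 0 of 35 unshifted simulated lists, which were drawn without correlation between genes and so do not test that assumption.

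Alternatives were RLE factors, upper-quartile factors, library sizes only, leaving out the 50 most abundant and the mitochondrial genes, 2 other filters, DESeq2 1.42.0, limma-voom, robust dispersion, a threshold of 0.01, a test against the fold minimum, a replicate block, a prior count of 0.5, and leaving out each of the 6 libraries. Figures were drawn with matplotlib 3.10.9.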

Results

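Gene expression was measured by RNA sequencing in livers of zebrafish (Danio rerio). The samples formed 2 groups of 3. The ATG5 group carried a transgene that expresses human ATG5, an autophagy gene, in the liver when the steroid mifepristone is given. The WT group was wild type and also received mifepristone, and all 6 samples carry the label 2 wpi. The comparison asks how livers of these transgenic fish differ from wild type under the same drug. No group carried the transgene without the drug, so an effect of ATG5 and other differences between the fish lines cannot be told apart. Expression of human ATG5 was not measured here. The series' design text describes the groups as hepatocellular carcinoma and normal liver. The total estimated count per library was 39447306, 33668961 and 44763253 in ATG5 replicates 1 to 3, and 36548978, 43864123 and 35151118 in WT replicates 1 to 3. The labels do not say whether replicates are separate animals or pools, so the p-values measure only the spread between these samples, which may be technical.

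The ATG5 livers had far higher expression of cell division, interferon and immune cell genes, and lower expression of genes for secreted liver proteins. THEMIS, known for its part in T cell development, stood at 384 ± 39.56 CPM (SD, n = 3) in ATG5 and 0.631 ± 0.305 in WT. That was far above the T cell genes cd4-1 and ZAP70 in ATG5 (22.9 ± 6.63 and 11 ± 2.94 CPM). Whether it came from T cells was not tested. The antiviral gene mxa stood at 121 ± 12.3 CPM against 0.648 ± 0.244. In the other direction, apoa1b, which encodes an apolipoprotein of high-density lipoprotein, stood at 25050 ± 5416 CPM against 91250 ± 8968. Of 20366 genes tested, 3530 were higher and 2701 lower in ATG5 (edgeR quasi-likelihood test, adjusted p under 0.05), and 2892 and 1705 of these had a log2 fold change of at least 1. The values of the 2 groups did not overlap for 49.3% of the tested genes, where chance gives 10%.

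The balance between higher and lower calls rested on the scaling. With TMM factors, 56.7% of the called genes were higher in ATG5. With library sizes only, all log2 folds moved up by a median of 0.94 and 94.9% of the calls were higher, 10853 against 578. The 10 most abundant genes took 16.45% to 17.71% of the counts in ATG5 and 25.22% to 27.69% in WT, and the TMM factors were 1.33 to 1.47 and 0.684 to 0.763. All changes below are relative to TMM scaling. Without WT replicate 1 the counts were 2217 higher and 1586 lower. Without ATG5 replicate 1 they were 2311 and 1614, and without ATG5 replicate 3 they were 2368 and 1799.

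Among other genes with large changes, WIF1, an inhibitor of Wnt signalling, had a log2 fold of 7.87 ± 0.38 (SE, n = 3 per group), and trim35-14 one of 8.14 ± 0.23. The WT mean of trim35-14 was 0.0498 ± 0.0261 CPM (SD), below 3 counts in a library. The SE is too small for such a gene, because the prior count of 2 narrows the spread near 0 counts. The pump gene atp1a1a.3 had no count in any WT library and 53.4 ± 35.7 CPM in ATG5, a log2 fold of at least 10.54 against a floor of 3 counts over the WT group. The neuronal adhesion gene slitrk3b had a log2 fold of -7.33 ± 0.28, and the tryptophan-degrading enzyme gene tdo2b one of -8.72 ± 1.21. In ATG5, slitrk3b had a mean of 0.101 ± 0.053 CPM (SD), so the limit given for trim35-14 applies to its SE. The acyl-CoA synthetase gene ACSF2 fell from 800 ± 40.2 to 131 ± 3.68 CPM.

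**Figure D1:**
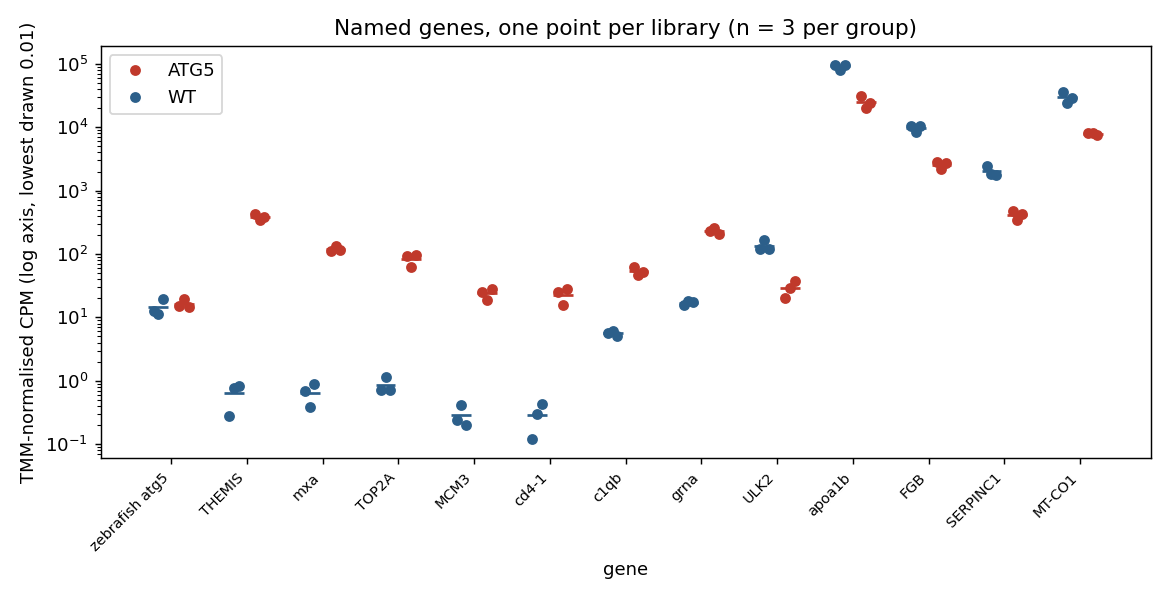
TMM-normalised CPM on a log axis for 13 genes, with 1 point per library, red for ATG5 and blue for WT, and a bar at each group mean. THEMIS stands at 384 CPM in ATG5 and 0.631 in WT, while zebrafish atg5 overlaps between the groups.

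The zebrafish's own atg5 gene did not pass the test. It stood at 16.4 ± 2.58 CPM in ATG5 and 14.6 ± 4.58 in WT, a log2 fold of 0.17 ± 0.28 (edgeR adjusted p = 0.65). With library sizes only it was 1.12 (adjusted p = 0.0131). The transgene is human ATG5, which a zebrafish transcript set need not hold. Whether any of its reads were counted for zebrafish atg5 was not tested, so this value cannot measure the transgene or check the labels. The test had limited reach here: on simulated counts with the fitted spread and 6000 changed genes, it recovered 30.6% of the genes changed 2-fold and 84.3% of those changed 4-fold, so a gene that did not pass is not shown to be unchanged.

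Genes of cell division rose together. In the mitosis list 58 of 64 tested genes rose and 0 fell, with a median log2 fold of 4.51, and 60 rose adjusted over the list alone. TOP2A, the topoisomerase of dividing cells, stood at 83.9 ± 17.9 CPM against 0.857 ± 0.242, and the kinase genes AURKB and bub1 had log2 folds of 6.25 ± 0.24 and 5.87 ± 0.18. In the DNA replication list 49 of 56 genes rose and 2 fell, with a median of 3.29 (51 and 2 adjusted over the list alone). MCM3, a part of the replicative helicase, had a log2 fold of 6.34 ± 0.32, and UHRF1 one of 3.87 ± 0.21. Both lists passed camera (adjusted p = 7.01e-25 and 1.17e-20), and neither passed with an estimated correlation (adjusted p = 0.113 for both).

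Interferon and immune cell genes were higher. In the interferon response list 35 of 44 genes rose and 0 fell, with a median log2 fold of 3.03, and IRF7, a transcription factor of that response, had a log2 fold of 4.02 ± 0.17. The camera adjusted p was 3.55e-14, and the adjusted p = 0.127 with an estimated correlation. In the antigen presentation list 24 of 34 rose and 1 fell (median 1.75), with cd74b at 287 ± 25.98 CPM against 31.1 ± 4.98 and tap2a at a log2 fold of 3.37 ± 0.24. In the inflammatory cytokine list 22 of 47 rose and 1 fell (median 1.19), with the chemokine gene ccl35.1 at 4.53 ± 0.25 and tnfrsf9a at 3.54 ± 0.20. Camera gave adjusted p = 1.18e-08 and 1.91e-07 for these lists, and adjusted p = 0.113 and 0.121 with an estimated correlation. The genes that rose numbered 36, 26 and 27 in these 3 lists when adjusted over the list alone, and 1 fell in each.

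Markers of blood-borne immune cells moved with those groups. Of the macrophage markers 32 of 40 rose and 2 fell (median 2.83), with c1qa at 42.2 ± 11.06 CPM against 3.61 ± 0.419, c1qb at a log2 fold of 3.26 ± 0.15, and SLC7A7 at 4.78 ± 0.27. The protease gene ctss2.1 had a log2 fold of 4.64 ± 0.26. Of the lymphocyte markers 20 of 38 rose and 0 fell (median 2.15), with the T cell genes cd4-1 and ZAP70 at 6.31 ± 0.52 and 5.17 ± 0.30. Of the neutrophil markers 10 of 19 rose and 1 fell (median 1.3), with srgn at a log2 fold of 1.299 ± 0.067. The camera adjusted p was 1.85e-12, 8.82e-06 and 0.000277 in this order, and the adjusted p = 0.121, 0.121 and 0.113 with an estimated correlation. The numbers that rose were 32, 24 and 12 adjusted over the list alone.

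Genes for proteins that the liver secretes were lower. In the plasma protein list 29 of 44 genes fell and 3 rose, with a median log2 fold of -1.38 that was -0.43 with library sizes only (16 lower, 5 higher). The apolipoprotein genes apoc1 and apobb.1 had log2 folds of -2.69 ± 0.07 and -1.76 ± 0.16. In the coagulation list 18 of 32 fell and 1 rose (median -1.41, and -0.47 with library sizes only, where 11 were lower and 6 higher), with the fibrinogen gene FGB at 2570 ± 354 CPM against 9779 ± 1203 and SERPINC1, which encodes antithrombin, at -2.27 ± 0.20. In the complement and acute phase list 18 of 48 fell and 5 rose (median -1.04, and -0.09 with library sizes only, where the balance turned to 8 lower and 14 higher); c3a.6 fell by 2.35 on the log2 scale, while the macrophage genes c1qa and c1qb of that list rose. The camera adjusted p was 7e-09, 2.4e-06 and 0.00825, and the adjusted p = 0.113, 0.235 and 0.342 with an estimated correlation. With library sizes only, camera with the preset correlation also passed these lists as lower than other genes (adjusted p = 1.55e-18, 1.34e-10 and 3.39e-07). The numbers that fell were 33, 18 and 18 adjusted over the list alone. Without the 50 most abundant and mitochondrial genes, 18 of the 31 plasma protein genes left and 13 of the 27 coagulation genes left fell, and the coagulation median was -0.87.

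Lists of liver metabolism also lay below other genes. In gluconeogenesis 12 of 21 genes fell and 1 rose (median -1.01, and -0.07 with library sizes only, where 6 were lower and 6 higher), and the glucose-6-phosphate transporter gene SLC37A4 had a log2 fold of -1.71 ± 0.16. In fatty acid oxidation 18 of 47 fell and 2 rose, with a median of -0.55 that turned to 0.39 with library sizes only (4 lower, 18 higher), and PPARA, a regulator of that pathway, had a log2 fold of -3.03 ± 0.47. In amino acid catabolism 24 of 63 fell and 5 rose (median -0.52, turning to 0.42, with 7 lower and 24 higher), with hpda at 1570 ± 299 CPM against 7805 ± 1103 and ARG2 at -3.22 ± 0.44. In cholesterol synthesis 9 of 26 fell and 1 rose (median -0.81, turning to 0.16, with 1 lower and 3 higher): ldlra, the receptor for low-density lipoprotein, had a log2 fold of -3.31 ± 0.42 and IDI1 one of 1.29 ± 0.13. Camera gave adjusted p = 0.000102, 9.55e-05, 0.000686 and 0.00543, and adjusted p = 0.113, 0.304, 0.491 and 0.491 with an estimated correlation. With library sizes only the median over all tested genes was 0.97. Camera with the preset correlation still passed these lists as lower than other genes there (adjusted p = 5.31e-06, 0.0113, 9.16e-05 and 1.27e-05). In these lists 13, 18, 26 and 9 genes fell adjusted over the list alone. ATG5 replicate 3 had the lowest mean level of the cholesterol synthesis list (-1.06 in centred log2 CPM, against -0.18 and 0.02 in the other ATG5 libraries), and without it the camera adjusted p of that list was 0.0439.

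The other metabolic lists were nearer the threshold. In bile acid metabolism 7 of 32 genes fell and 4 rose (median -0.41), with slc27a2a at a log2 fold of -2.80 ± 0.17. In xenobiotic metabolism 17 of 81 fell and 7 rose (median -0.42), with the cytochrome gene cyp2aa7 higher at 6.84 ± 0.71. In lipogenesis 12 of 41 fell and 3 rose (median -0.40), with DGAT2, an enzyme of triglyceride synthesis, at -2.10 ± 0.17. The 3 medians turned to 0.53, 0.52 and 0.55 with library sizes only, where 4, 6 and 4 genes were lower and 12, 23 and 13 higher. The groups overlapped in the mean log2 CPM of these lists, centred over the libraries. WT replicate 2 lay within the range of the ATG5 libraries for bile acid metabolism (-0.23 against -0.25 to -0.08) and xenobiotic metabolism (-0.07 against -0.09 to -0.04), and ATG5 replicate 2 lay above WT replicate 1 for lipogenesis (0.17 against -0.05). Camera gave adjusted p = 0.0307, 0.0256 and 0.0354, and adjusted p = 0.16, 0.471 and 0.501 with an estimated correlation. With library sizes only, camera with the preset correlation still passed the 3 lists as lower than other genes (adjusted p = 0.0035, 6.64e-05 and 0.0027). The lipogenesis call was lost without ATG5 replicate 1 (adjusted p = 0.0605), ATG5 replicate 3 (0.0737) or WT replicate 3 (0.0851), and with a stricter filter (0.0537). Likewise lost were the bile acid call without WT replicate 1 (0.0613), and the xenobiotic call without WT replicate 3 (0.0566). Adjusted over the list alone, 9, 17 and 12 genes fell.

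Relative to TMM scaling, more autophagy genes fell than rose, and more lysosome genes rose than fell. In the autophagy list 15 of 55 genes fell and 4 rose, with a median log2 fold of -0.32 that turned to 0.62 with library sizes only, where 29 genes were called higher and 2 lower. ULK2 and atg9b, which act early in autophagosome formation, had log2 folds of -2.22 ± 0.30 and -1.92 ± 0.24, and ULK1 one of -1.45 ± 0.14, whose call was lost with library sizes only (adjusted p = 0.0761). TFEB, a transcription factor for lysosome and autophagy genes, rose by 2.49 ± 0.28. In the lysosome list 30 of 58 genes rose and 5 fell (median 0.62), with the protease genes CTSB at 515.5 ± 60.6 CPM against 161 ± 4.15 and CTSK at 3.70 ± 0.20 and grna, a progranulin gene, at 3.76 ± 0.10. Markers of macrophages, cells rich in lysosomes, rose beside that list (32 of 40, median 2.83). In the proteasome list 25 of 39 rose and 0 fell (median 0.84), with PSMB5 at 1.21 ± 0.16. Camera gave adjusted p = 0.00543 for autophagy, 0.000894 for the lysosome and 2.09e-07 for the proteasome, and adjusted p = 0.491, 0.43 and 0.491 with an estimated correlation. The autophagy call was lost with library sizes only (adjusted p = 0.679), where the lysosome and proteasome medians were 1.57 and 1.79, with 46 and 38 genes called higher and 0 lower in both. The difference between the autophagy and lysosome lists was not tested. Adjusted over the list alone, 19 autophagy genes fell, and 32 lysosome and 26 proteasome genes rose.

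Growth factor, clock and glucocorticoid response genes were lower relative to TMM scaling. In the growth factor list 23 of 47 fell and 1 rose (median -0.78), with IGFALS, which binds circulating insulin-like growth factors, at 129.7 ± 27.1 CPM against 683 ± 83.1. In the circadian clock list 17 of 37 fell and 4 rose (median -0.81): dbpa, nr1d2a and nfil3-6 had log2 folds of -1.88 ± 0.09, -1.72 ± 0.17 and -1.94 ± 0.20, and NFIL3 one of 2.27 ± 0.18. In the glucocorticoid response list 15 of 30 fell and 2 rose (median -0.94), with KLF9 at -2.49 ± 0.20. All 3 medians turned to values above 0 with library sizes only (0.16, 0.14 and 0.02), where 9, 3 and 5 genes were lower and 12, 8 and 5 higher. In that setting the median over all tested genes was 0.97. Camera there still passed the 3 lists as lower than other genes (adjusted p = 1.6e-07, 3.32e-05 and 8.22e-07). Camera gave adjusted p = 8.66e-08, 0.000145 and 0.000686, and adjusted p = 0.113, 0.113 and 0.121 with an estimated correlation. A total of 27, 19 and 15 genes fell adjusted over the list alone. The sample titles give no time of day, so a difference in collection time between the groups was not tested.

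**Figure D2:**
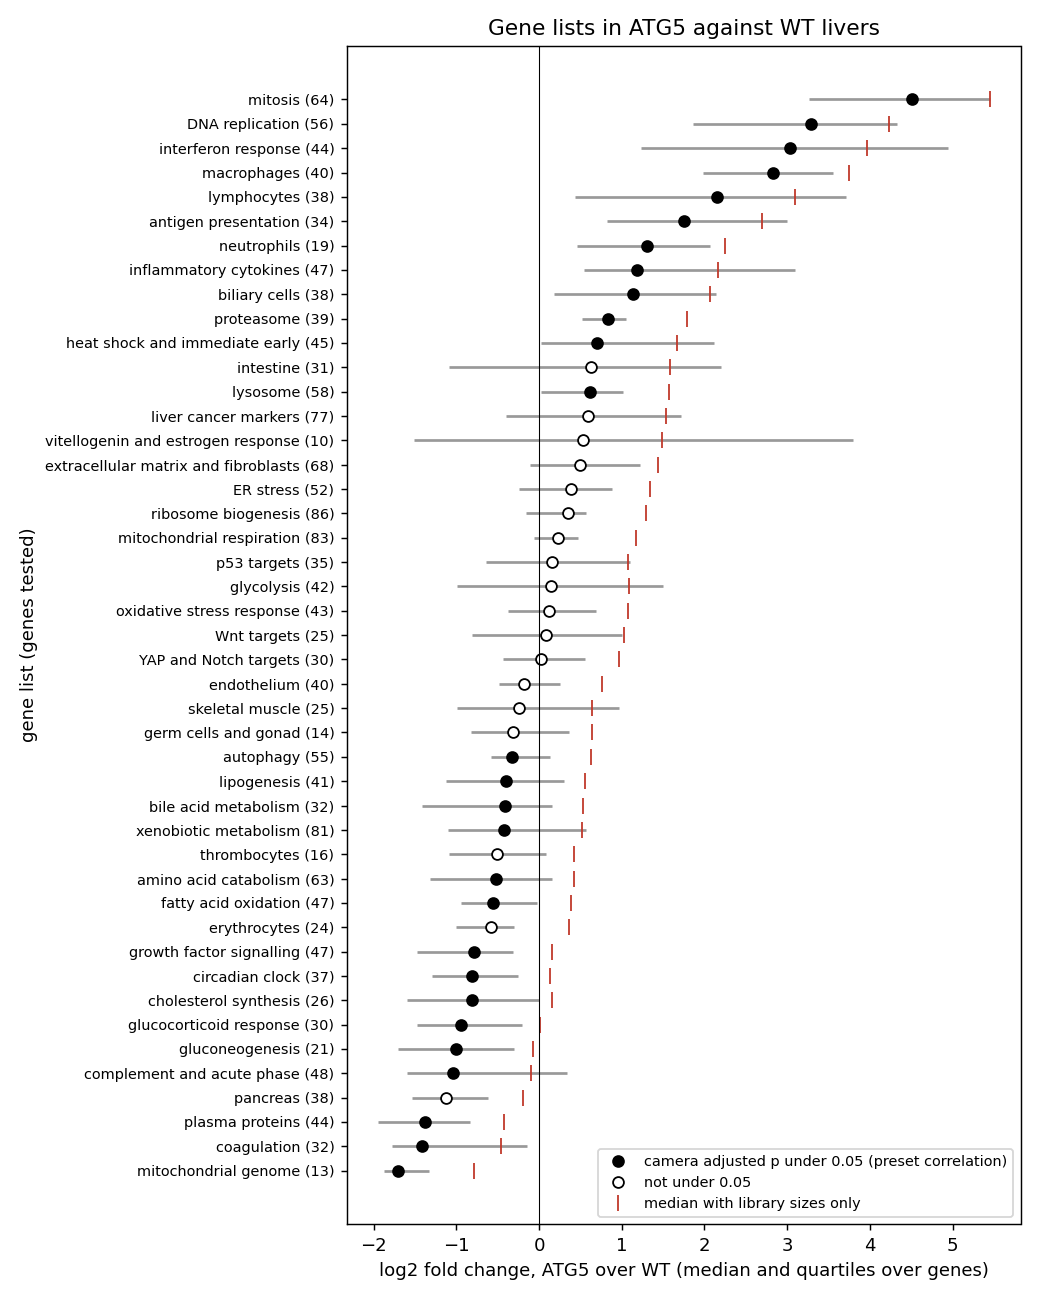
Median log2 fold change, ATG5 over WT, of each of the 45 gene lists, with lines from the first to the third quartile over genes, filled points for a camera adjusted p under 0.05 and red ticks for the median with library sizes only. Mitosis lies highest at 4.51 and the mitochondrial genome lowest at -1.71; with library sizes only the medians move up, and those of autophagy and fatty acid oxidation turn from below 0 to above 0.

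Other cell types and signs of sample quality differed between the groups too. All 13 genes of the mitochondrial genome fell (median -1.71, and -0.79 with library sizes only), with MT-CO1 at 7905 ± 271 CPM against 29780 ± 5781; mitochondrial counts were 3.45% to 3.57% of each ATG5 library and 5.6% to 5.88% of each WT library. Of the biliary markers 20 of 38 rose and 2 fell (median 1.13), with cldn7b at a log2 fold of 5.40 ± 0.51. In the heat shock and immediate early list 16 of 45 rose and 3 fell (median 0.70), with ier2a at 2.23 ± 0.15. Camera gave adjusted p = 7e-09, 0.000562 and 0.0193, and adjusted p = 0.113, 0.342 and 0.349 with an estimated correlation. The heat shock call was lost without WT replicate 3 (adjusted p = 0.0582) and with library sizes only (0.142). Adjusted over the list alone, 13 mitochondrial genes fell, and 20 biliary and 18 heat shock genes rose.

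The remaining cell type lists did not pass camera with TMM scaling. With library sizes only, 19 endothelium, 18 intestine and 43 extracellular matrix genes were called higher and 1, 5 and 2 lower. Of the endothelium markers 5 of 40 rose and 7 fell (median -0.18, camera adjusted p = 0.263), and of the erythrocyte markers 1 of 24 rose and 1 fell (-0.58, 0.212). Of the thrombocyte markers 1 of 16 rose and 2 fell (-0.50, 0.271), and of the pancreas markers 1 of 38 rose and 1 fell (-1.12, 0.257). The medians of the first 3 turned to 0.76, 0.36 and 0.42 with library sizes only, where the median over all tested genes was 0.97. In that setting the erythrocyte, thrombocyte and pancreas lists passed camera as lower than other genes (adjusted p = 0.0156, 0.0153 and 7.78e-05). The direction of the pancreas list rested on the WT libraries kept: their mean levels in centred log2 CPM were -2.26, 1.03 and 1.54, on either side of the ATG5 libraries (-0.21 to 0.02). Without WT replicate 1 the list passed as lower (adjusted p = 3.09e-09), without WT replicate 2 it was lower with 0.717, and without WT replicate 3 it turned to higher with 0.838. Intestine (5 of 31 rose, 6 fell, 0.972), germ cells and gonad (1 of 14, 3, 0.564, and lower with 0.0146 without WT replicate 3 or 0.0487 with library sizes only) and skeletal muscle (5 of 25, 2, 0.874) did not pass either. In the extracellular matrix and fibroblast list 15 of 68 rose and 4 fell (camera adjusted p = 0.0634, and higher with 0.0191 without WT replicate 1 or 0.0294 without ATG5 replicate 3). That list also passed as higher without the most abundant genes (adjusted p = 0.0356), with a stricter filter (0.0346) and with limma-voom (0.0403). In it, 1 gene with the symbol FN1 (ENSDARG00000006526), a fibronectin gene, fell from 17310 ± 2153 to 2026 ± 336 CPM. Of the vitellogenin and estrogen response genes 2 of 10 rose and 2 fell (camera adjusted p = 0.988): vtg1 had a log2 fold of 5.43 ± 0.76, a call lost with limma-voom (adjusted p = 0.0642), and ESR1 one of -2.64 ± 0.64. The second vitellogenin gene that rose, vtg4, had a log2 fold of 4.83 ± 1.11. That call was lost without ATG5 replicate 3, WT replicate 1 or WT replicate 3 (adjusted p = 0.0726, 0.0806 and 0.0551) and with limma-voom (0.119). The labels give no sex of the fish, so a difference in sex between the samples was not tested.

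The pancreas gene that rose was CELA1 (ENSDARG00000017314), an elastase gene with a second gene of the same symbol. It stood at 12350 ± 4727 CPM in ATG5 and 708 ± 632.5 in WT, a log2 fold of 4.12 ± 1.44 (edgeR adjusted p = 0.0317). The call was lost without any 1 of ATG5 replicates 1, 2 and 3 (adjusted p = 0.0721, 0.0754 and 0.0591) or WT replicates 2 and 3 (0.0908 and 0.0514), and with a replicate block (0.0676). The amylase gene amy2al1 fell by 1.29 on the log2 scale, a call lost with library sizes only (adjusted p = 0.218). The trypsin gene prss1, chosen after its values were seen, stood at 169.8 ± 47.1 CPM in ATG5 and 487 ± 455 in WT (adjusted p = 0.306, and 0.0252 without WT replicate 1).

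**Figure D3:**
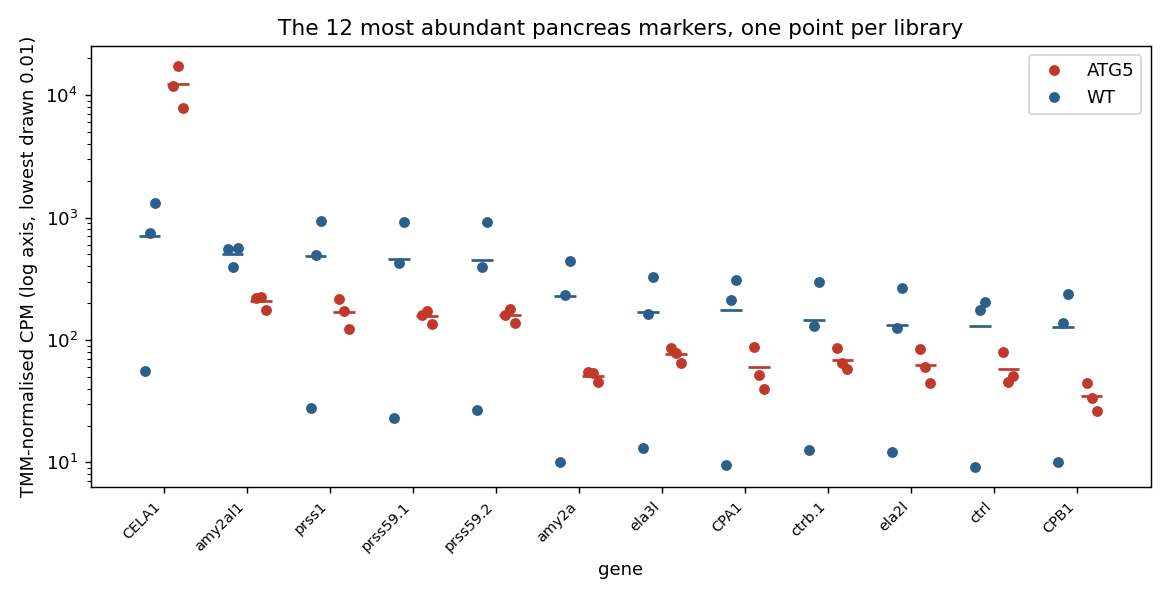
TMM-normalised CPM on a log axis for the 12 most abundant pancreas markers, with 1 point per library, red for ATG5 and blue for WT, and a bar at each group mean. CELA1 stands at 12350 CPM in ATG5 and 708 in WT, while prss1 stands at 169.8 and 487.

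Relative to TMM scaling, stress, energy and cancer lists held members that went both ways. With library sizes only the calls in them were mostly higher: 22 higher and 3 lower in glycolysis, 29 and 4 in oxidative stress, 36 and 0 in ER stress, 74 and 0 in mitochondrial respiration, and 68 and 0 in ribosome biogenesis. The same setting gave 20 and 2 for p53 targets, 13 and 2 for Wnt targets, 18 and 0 for YAP and Notch targets, and 51 and 5 for liver cancer markers. With TMM, in glycolysis 14 of 42 rose and 10 fell (camera adjusted p = 0.742), in oxidative stress 11 of 43 rose and 6 fell (0.708), with CAT, which encodes catalase, at a log2 fold of -1.75 ± 0.11, and in ER stress 13 of 52 rose and 8 fell (0.271), with PSAT1 at 3.95 ± 0.29. In mitochondrial respiration, encoded in the nucleus, 10 of 83 rose and 4 fell (0.0967, and higher with 0.0271 without ATG5 replicate 2 or 0.0207 without WT replicate 3, 0.029 with limma-voom and 0.000124 with library sizes only), with cox6a1 at 2.00 ± 0.21, and in ribosome biogenesis 15 of 86 rose and 7 fell (0.128, and higher with 0.038 without WT replicate 2 or 0.0114 with library sizes only). Of the p53 targets 11 of 35 rose and 4 fell (0.564), with fas at 3.18 ± 0.19 and TP53INP1 at -2.36 ± 0.24. Of the Wnt targets 5 of 25 rose and 5 fell (0.838), and of the YAP and Notch targets 6 of 30 rose and 5 fell (0.666). Of the liver cancer markers 26 of 77 rose and 14 fell (0.0996, and higher with 0.0329 without WT replicate 1), with s100a10b at 2.69 ± 0.12 and the liver transcription factor gene FOXA2 at -1.64 ± 0.15.

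The libraries separated by group. Pearson correlations of log2 CPM over the tested genes were at least 0.913 within a group and at most 0.847 between groups, and the first principal component held 56.9% of the variance. Of the 45 lists, 27 passed camera with its preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.113. Most lists had an estimate above the preset 0.01, but a higher correlation does not by itself account for that loss. The estimates for growth factor signalling and gluconeogenesis were 0.0016 and -0.019, under the preset. Their unadjusted camera p still rose from 1.54e-08 to 0.00274 and from 3.18e-05 to 0.0104. fry, which tests each list on its own, also passed 27, with p53 targets, liver cancer markers and extracellular matrix in place of lipogenesis, cholesterol synthesis and xenobiotic metabolism. For the vitellogenin, Wnt, and YAP and Notch lists the median and mean lay above 0 and the camera direction was down, while fry gave up. For endothelium, germ cells and skeletal muscle the median lay below 0 and the mean above 0, with fry up for the last 2 of these, and for intestine both lay above 0 while fry gave down. None of these 7 lists passed camera or fry, and leaving out 1 library turned the camera direction of the vitellogenin, Wnt, YAP and Notch, intestine and skeletal muscle lists.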

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

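With library sizes only, 10853 genes were higher and 578 lower, 8879 passed the fold minimum, and zebrafish atg5 passed with a log2 fold of 1.12; this setting leaves the difference in library composition in every fold. At an adjusted p under 0.01 the counts were 1519 higher, 955 lower and 2323 past the fold minimum, and a test against a log2 fold of 1 left 1854. The other scalings and filters, limma-voom, robust dispersion and DESeq2 gave counts within 1.5 times the reported ones, with 4046 higher and 3637 lower by DESeq2. Leaving out each library in turn gave 2217 to 2791 higher, 1586 to 2071 lower, 3313 to 3962 past the fold minimum, 26 to 29 lists, and a log2 fold of atg5 of 0.00818 to 0.446; each such fit has fewer samples. With an estimated correlation 0 of the 45 lists passed camera, and 45 lists kept their side of the threshold with RLE factors, upper-quartile factors, a prior count of 0.5 or no filter. The first principal component held 54% with a prior count of 0.5 and all tested genes; the cause was not tested. Robust dispersion does not enter the list test. The replicate numbers showed no sign of pairing the samples: deviations of same-numbered libraries correlated at -0.0407, -0.0999 and 0.0212, and not every library correlated best with its own number. With so few libraries this cannot exclude a shared day, tank or clutch. With the replicate block 2252 genes were higher and 1635 lower, and the extracellular matrix and erythrocyte lists passed camera as higher and lower than other genes (adjusted p = 0.0331 and 0.0122). Depth limits statements on genes near 3 counts.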

Other observations

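The tests of explanations below, except that of neighbouring genes, and the splits of the samples were chosen after the result was seen. A total of 93 called genes without overlap between the groups had a mean of at least 5 CPM in one group and at most 0.2 in the other. Of these, 83 were higher in ATG5 and 10 lower, slitrk3b among the latter. Beside the rise of vtg1 and vtg4, the more abundant vitellogenin gene vtg5, chosen after its values were seen, stood at 355 ± 217 CPM in ATG5 and 427 ± 145 in WT (edgeR adjusted p = 0.756), and its log2 fold of -0.27 was 0.69 with library sizes only.

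Plasma protein genes were lower and macrophage genes higher in ATG5. A lower share of hepatocytes as the whole cause would raise the markers of every other cell type alike. The median log2 fold of macrophage markers instead exceeded that of endothelium markers by 3.01. A permutation test over genes gave a two-sided p = 1e-05, the smallest that 100000 permutations can give, but genes are not independent. The pair of lists was picked after their medians were seen, so this p is no independent support. Per library the difference was 2.53 ± 0.34 (SD, n = 3) in ATG5 and -0.50 ± 0.30 in WT. Endothelium was the only comparator. Biliary markers also rose (20 of 38 higher and 2 lower, median 1.13), so a lower hepatocyte share as part of the cause stays open. The choice of TMM scaling alone did not put the plasma protein genes below 0, since their median was -0.428 with library sizes only. The 95% bootstrap interval over genes was -0.821 to -0.153, which leaves out the spread between libraries. Their median log2 CPM per library in that setting was lower in every ATG5 library. The difference between group means was -0.705 (SD 0.19 in ATG5 and 0.04 in WT, n = 3 each). That setting measures shares of the counts, and the median over all tested genes was 0.97 there. A share can fall because other RNAs rise, so a lower amount of these RNAs was not shown. More macrophages and lymphocytes in the ATG5 livers, or changed expression within cells, stay open as hypotheses, and neither was tested.

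CELA1 was higher in ATG5. Pancreas tissue of the kind in the WT samples would keep CELA1 in 1 ratio to the other 37 pancreas markers, but the log2 ratio of CELA1 to their sum was 3.07 ± 0.45 (SD, n = 3) in ATG5 and -2.81 ± 0.91 in WT, a difference of 5.88 with no overlap between the groups. If pancreas were the only source of CELA1, this ratio would not depend on how much pancreas a library holds, which differed widely between the WT libraries. The WT ratios still spread from -3.86 to -2.25. The lowest was that of WT replicate 1, which also had the lowest level of pancreas markers (-2.26 in centred log2 CPM). The difference between the groups was larger than this spread. CELA1 was taken up as the 1 pancreas marker of 38 called higher, so some difference in this ratio followed from that choice. Reads moved from the other tested genes with an elastase symbol are too few: these 9 genes held 422 CPM in WT, 3.62% of the rise of CELA1. Elastase genes without such a symbol were not counted, so reads moved from them were not tested. Genes with no symbol held 3.39% to 3.55% of the counts of the WT libraries. Pancreas cells with changed expression or a response to the transgene stay open and were not tested, and the call itself rested on all but 1 of the libraries.

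Genes on in one group and near 0 in the other may reflect stretches of chromosome that differ between the fish lines. They include members of the mitosis and interferon response lists reported above, such as bub1, KIF23, ifit9 and mxb. Of the 58 such genes that could be placed, 8.62% had another among the 10 genes on either side, where random sets gave a median of 3.45% and a 95th percentile of 10.3%. The share lay between the median and the 95th percentile, where the prediction made beforehand decides neither way. The test is also void, because 62.4% of the genes could be placed by symbol, under the 80% that it took as a minimum. Line differences and an effect of the transgene therefore cannot be told apart.

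The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 6231 genes and the highest of the others 1, with 1 split as large. With the fold minimum the real split called 4597 and the highest other 1. Every other split holds libraries of both groups on each side, in unequal number. Part of the difference between ATG5 and WT stays in it, and the mixing widens the spread within its sides, which lowers gene calls. For gene lists with the preset correlation the real split passed 27 and the others 17 to 25. None of the other splits is free of the group difference, so these counts decide little about the grouping by themselves.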
